A study of Mus musculus with 9 samples.

How the data were processed

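Polyadenylated RNA of 9 mouse populations was made into strand-marking (dUTP) libraries and sequenced, per the labels' protocols. Aligner STAR 2.4.2a and genome build mm10 are named in the submitters' processing notes. The program that counted reads, the RefSeq release and whether counting used the strand are not given in the sources used here, so genes that overlap others or lie antisense to them are uncertain. Each deposited table holds, per the file headers, whole-number read counts and RPKM values for 26049 groups of RefSeq transcripts, the same rows in every table. The authors' counts are raw reads per transcript group. The authors' RPKM values are reads scaled to transcript length and to a total number of reads. Of 4770 rows over 100 reads in every library, 413 had RPKM not proportional to counts within 1%, none of them a single-transcript row. Start positions were read as 1-based, since 13623 rows began at a GENCODE M21 transcript start as given and 1068 after adding 1. Coordinates are mm10, from the row with most reads for a symbol.

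Counts of the 2050 symbols with several rows were summed, as were their RPKM values, which gave 23335 symbols. The 287 rows naming several symbols were kept under their joint name, and copies such as Mcpt1, Mcpt2 and Mcpt4 or the hemoglobin genes can share reads. CPM values were computed with edgeR 4.0.16 TMM factors in R 4.3.3. The factor was 0.753 in MMC9, where Mcpt1, Mcpt2, Mcpt4 and Cpa3 took 12.2% of reads, and 0.925 to 1.16 in the others. The ribosomal RNA row Rn45s took 0.143% to 1.33% of reads and was kept in library sizes. Depth ran from 5807400 reads on genes in MMC9 to 13744302 in CD4 Th2 cells, so 3 reads, the limit that a count of 0 allows, equal 0.686 CPM in MMC9 and 0.217 in BMMC. Intervals are 95% exact Poisson intervals of a count and exact binomial (Clopper-Pearson) intervals of a ratio of 2 counts, from scipy 1.17.1. No molecular identifiers are described for these reads, so intervals and limits cover counting error only. A ratio against 0 reads was taken against 3 reads and is given as "at least", and with 1 to 3 reads the ratio has its interval. Such a bound leaves out the counting error of the higher count and is not a 95% limit. The exact 95% lower limit was 445-fold where Rab38 is given as at least 548-fold above ILC2s. It was 165017-fold where Mcpt1 is given as at least 202910-fold above CD8 T cells.

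With 1 library per population, no test between populations was made and no p-value is given. Genes were counted by size, at 4-fold or more against each comparator, with 50 reads and 5 CPM in the higher library and the lower count set to at least 3 reads. Comparisons were MMC9 against the cultured mast cells, the intestinal type 2 cells (CD4 Th2 cells, ILC2s and the library labelled eosinophil) and the lymph node lymphocytes, all mast cells against all other libraries, each population against the rest, and the cultures in pairs. Genes were named by rule among those with 20 CPM in the higher libraries, by the largest smallest fold: 12 higher and 12 lower for the first comparison, 10 and 10 for the second, 5 and 5 for the third and each pair of cultures, 10 and 5 for shared genes and 5 per population. Predicted genes, clone-named genes, small RNAs and receptor or immunoglobulin segments were skipped, and any list member or any of the 5 genes with most reads in a library could be named. The 33 gene lists, the rule, the comparisons and all alternatives but the one without the library labelled eosinophil were fixed before the data were examined. Members with an older symbol in the tables (Siglec5, Emr1, Igj, Sc4mol and Sfpi1) were matched by hand. A list's value is the median over members with 10 reads in a compared library of log2(CPM + 1) minus the comparators' mean, with its percentile among 10000 random lists of the same size, drawn with replacement within 10 bins of mean expression, as a description of these libraries. List members were counted as higher or lower at 2-fold against each comparator with 20 reads in the higher library.

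The size rule was tested on simulated counts for 23335 genes, 200 of them altered in MMC9. All simulated libraries had the same expression profile with added noise and were scaled by their totals. Only genes with at least 100 expected MMC9 reads were altered. Recovery near the 50-read minimum and false calls between populations of unlike composition were therefore not measured. Of 80 genes raised 8-fold, 79 were recovered against the cultured mast cells, 78 against the intestinal type 2 cells and 77 against the lymph node lymphocytes. Of 80 lowered 8-fold, 78, 75 and 80 were recovered, no gene raised 2-fold and no unaltered gene passed. Alternatives were DESeq2 1.42.0 size factors, plain CPM, RPKM, lower and higher read minimums (10 reads, or 200 reads and 20 CPM), 2-fold and 8-fold, a counting interval wholly past 4-fold, the row with most reads per symbol, scaling without the 20 genes of highest share and leaving out each comparator, with other pseudocounts (0.1 and 5) and a minimum of 100 reads for lists and similarity.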

Results

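RNA from 9 sorted or cultured mouse hematopoietic populations was sequenced, with 1 library per population. The populations were chosen to place MMC9s, the IL-9-producing mucosal mast cells of the small intestine in food allergy, beside other mast cells and beside the lymphocytes, innate lymphoid cells and eosinophils of the same disease model. MMC9s (low integrin beta7, c-Kit, ST2 and high-affinity IgE receptor positive), CD4 Th2 cells (IL-17RB and ST2 positive), group 2 innate lymphoid cells (ILC2s) and a population labelled eosinophils were sorted from the small intestine of food-allergic mice. That last library held Epx at 0.744 CPM and Siglec5 at 21.8, and its eosinophil list summed to 603 CPM, against 1326 in BMMC. Its epithelial genes summed to 10652 CPM, and it is called the library labelled eosinophil. The mast cell progenitor library (MCP) came from cells with high integrin beta7 sorted from the small intestine and then expanded for 2 weeks in stem cell factor and IL-3, so it describes a culture and not fresh progenitors. Peritoneal mast cells (peritoneal MMC), from mice injected with a substance labelled zymogen, were cultured for 2 weeks in the same cytokines, and bone marrow-derived mast cells (BMMC) were grown from naive bone marrow for 4 weeks. CD19+ B cells and CD8+ T cells came from mesenteric lymph nodes. Reads on genes numbered 12238774 in BMMC, 5807400 in MMC9, 11787505 in MCP, 10475632 in peritoneal MMC, 9058271 in B cells, 6691536 in CD8 T cells, 13744302 in CD4 Th2 cells, 6226782 in ILC2s and 6952702 in the library labelled eosinophil. No population had a replicate, so no difference below has a replicate check and none was tested between populations. Values are TMM-scaled CPM (read counts scaled to library size), brackets after a CPM or fold hold 95% exact intervals that cover counting error only, and a gene was counted as higher or lower at 4-fold or more against each comparator.

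The first comparison set MMC9s against the 3 cultured mast cell libraries. MMC9s carried mucosal mast cell chymases at levels that the cultured cells did not approach. Mcpt1, a chymase of mucosal mast cells (chromosome 14, 56017964 to 56020391, mm10), stood at 85594 CPM (85319.9 to 85869) and had 6 reads in BMMC, 20 in MCP and 6 in peritoneal MMC. Mcpt1 was 46675-fold (30221 to 76413) higher in MMC9 than in MCP, the nearest culture. Mcpt2 (chromosome 14, 56042123 to 56044634) was at 33301 CPM, 537-fold (498 to 580.3) above MCP, and Mcpt9 (chromosome 14, 56026864 to 56030495) was at 99.8 CPM, at least 357-fold above peritoneal MMC. All 3 of 3 measured members of the mucosal protease list were at least 2-fold higher than in each culture (median log2 difference 10.77, percentile 100 among 10000 matched random lists). Mcpt4, a chymase usually assigned to connective tissue mast cells (chromosome 14, 56059744 to 56062310), was also higher at 15732 CPM, against 2480.1 in peritoneal MMC, 450.5 in MCP and 14.4 in BMMC. Cma1 went the other way against MCP and peritoneal MMC, with 4658 CPM in MMC9, 14345 in MCP, 13858 in peritoneal MMC and 3095 in BMMC. Over the connective tissue mast cell list, 3 of 11 members were higher and 0 lower (median log2 difference -0.67, percentile 1.03). Mcpt1, Mcpt2 and Mcpt4 have similar sequences, and reads shared between them leave the split among them uncertain. Mcpt9, from the same stretch of chromosome 14, had 436 reads in MMC9 beside 374058 for Mcpt1. Whether its reads are its own was not tested.

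**Figure D1:**
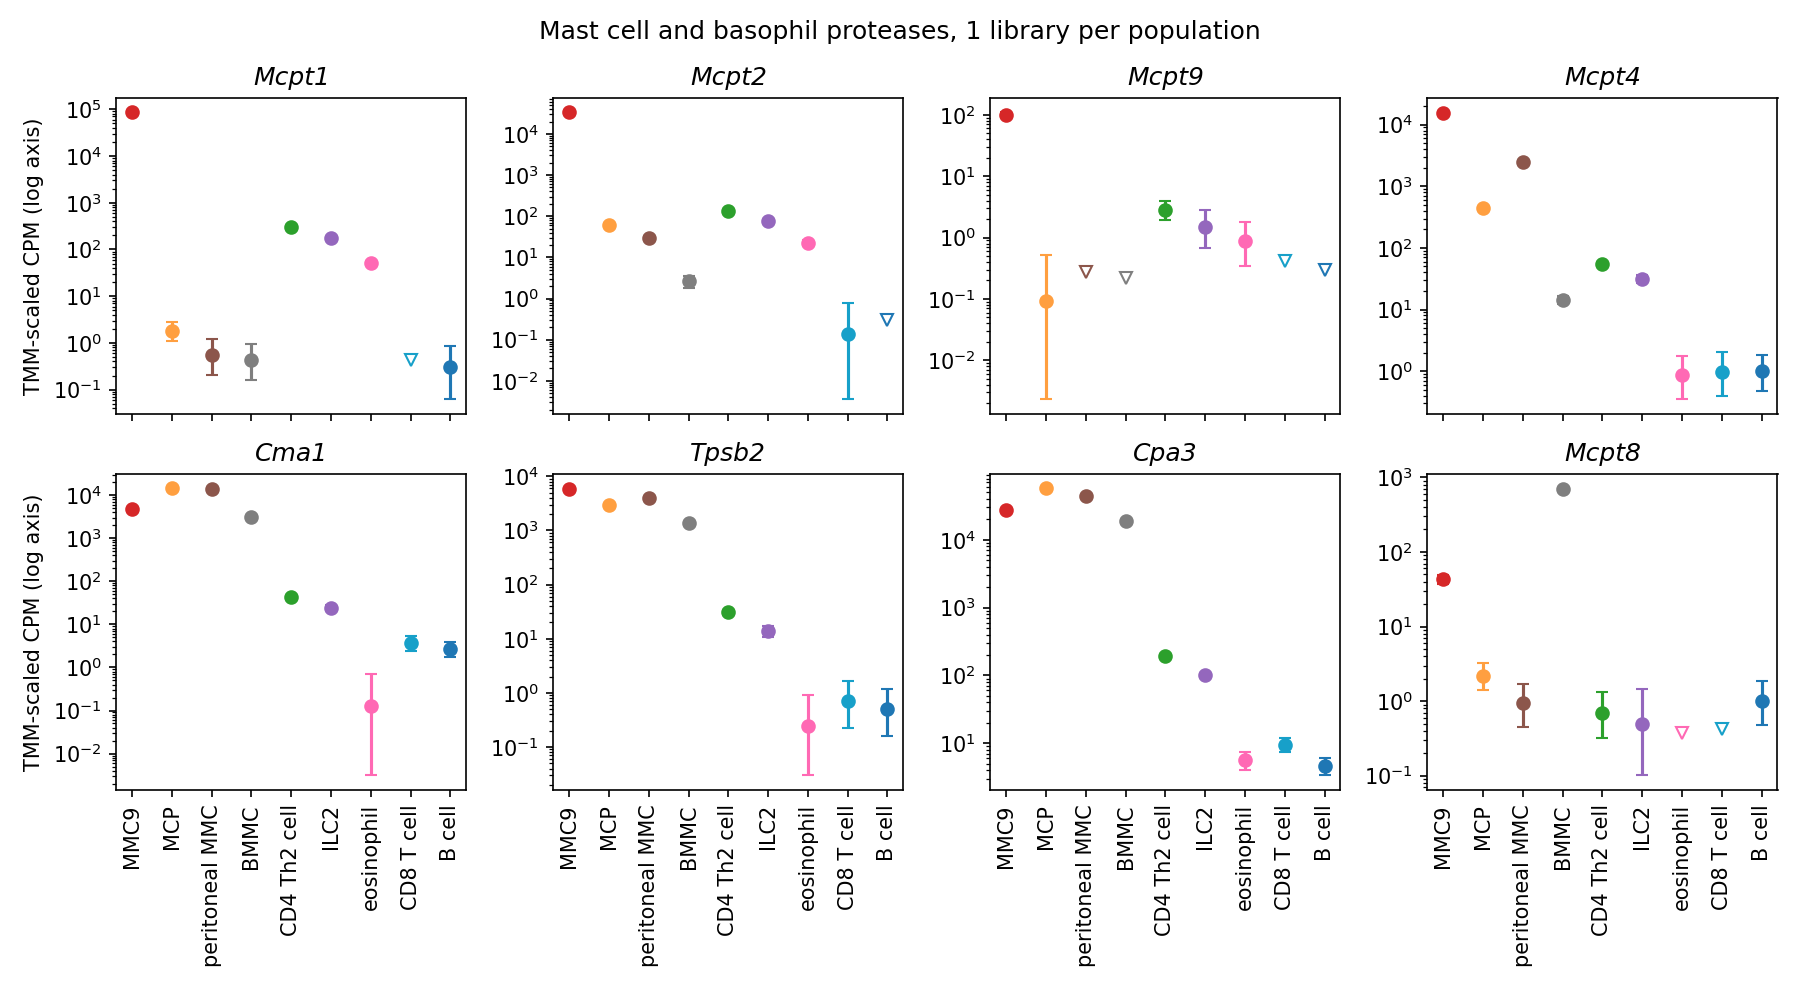
Mast cell and basophil protease levels in the 9 libraries, on a log axis of TMM-scaled CPM. Points are single libraries, bars are 95% exact Poisson intervals (counting error only), and open triangles mark the level of 3 reads in a library with 0 reads. Mcpt1 lies at 85594 CPM in MMC9 and at or below 1.83 CPM in the 3 cultured mast cell libraries.

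Genes for amine and mediator synthesis separated MMC9s from the cultures less uniformly. Hdc, the enzyme that makes histamine, was at 10270.4 CPM (10176 to 10366) in MMC9 and at 363 CPM in BMMC, the highest culture, a ratio of 28.3-fold (27.5 to 29.1). Tph1, the first enzyme of serotonin synthesis, was at 10657 CPM in MMC9, 8395 in MCP and 5247 in peritoneal MMC. Ptgs2, the inducible cyclooxygenase, was at 429 CPM against 5.73 in BMMC, 0.183 in MCP and 0.0930 in peritoneal MMC. Of the amine and eicosanoid list, 4 of 17 members were at least 2-fold higher and 0 lower than in each culture (median log2 difference 0.29, percentile 87.1). The mast cell core list had 4 of 20 members higher and 0 lower (median log2 difference 1.05, percentile 100), and Smpx was the largest of these, at 638 CPM against 11.7 in MCP. The granule protease list had 8 of 16 higher and 1 lower (median log2 difference 2.81, percentile 100), among them Gzmb, a cytotoxic granule protease, at 3319.6 CPM. Genes of heparin and proteoglycan synthesis had 3 of 19 higher and 2 lower (median log2 difference 0.41, percentile 97.3), and genes of IgE receptor signalling had 4 of 25 higher and 1 lower (median log2 difference 0.59, percentile 99.5), with Itk, a T cell and mast cell kinase, at 1171 CPM in MMC9.

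Type 2 cytokines and several other secreted factors were higher in MMC9s than in any culture. Of the type 2 cytokine list, 4 of 5 measured members were at least 2-fold higher (median log2 difference 4.24, percentile 100). Il13 was 30.1-fold (26.0 to 35.0) and Il4 11.3-fold (9.46 to 13.5) above MCP, the highest culture for each, while Il9 had 120 reads in MMC9 and 0 in all 3 cultures. Ccl1, Ccl3 and Ccl4, chemokines for monocytes and T cells, were at 149, 526 and 840.5 CPM. Ccl4 was 211-fold (162 to 280.4) above BMMC and Ccl1 161-fold (86.8 to 336) above peritoneal MMC. The chemokine list as a whole had 3 of 16 members higher and 0 lower (median log2 difference 0.05, percentile 92.6). Among other cytokines 8 of 20 were higher and 3 lower (median log2 difference 0.94, percentile 99.99), including Il6 at 825 CPM against 50.5 in BMMC, and Lif at 678 CPM against 113 in BMMC, the highest culture. Cytokine receptors had 4 of 26 higher and 1 lower (median log2 difference 0.43, percentile 99.3), and with the authors' RPKM the median was -0.18. Of the lineage transcription factors 10 of 41 were higher and 0 lower (median log2 difference 0.68, percentile 100). Irf4, a regulator of cytokine genes in T cells, was at 313 CPM (297 to 331) against 16.1 CPM in BMMC, 0.183 in MCP and 0.186 in peritoneal MMC, and Batf, its binding partner, was at 417 CPM in MMC9 and 49.2 in MCP.

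Immediate early genes moved with these groups. Of 29 measured immediate early and stress genes 26 were at least 2-fold higher in MMC9 than in each culture and 0 were lower (median log2 difference 5.19, percentile 100). Nr4a1 was 262-fold (216 to 322) above peritoneal MMC, Nr4a3 201-fold (136 to 312) above BMMC, and Egr1 stood at 5073 CPM in MMC9, 314 in MCP and 683 in peritoneal MMC. The summed level of the list was 38122 CPM in MMC9, 24662 in ILC2, 14279.8 in CD4 Th2 and 11643 in the library labelled eosinophil, the 4 libraries sorted directly from the intestine. It was 1088 in BMMC, 2347 in MCP, 3499.8 in peritoneal MMC, 2749 in B cells and 1856 in CD8 T cells. MMC9s were sorted without culture and all 3 comparators were cultured, so population and culture cannot be told apart in this comparison. Markers of other intestinal cells also differed, with 14 of 20 epithelial members (median log2 difference 2.88, percentile 100) and 5 of 9 pancreatic members (median log2 difference 2.36, percentile 100) at least 2-fold higher in MMC9. Fcgbp, a goblet cell mucus protein, is among the named genes, with 114 CPM in MMC9, 151 in ILC2 and 596 in the library labelled eosinophil, where 24 of 26 epithelial members were highest.

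**Figure D2:**
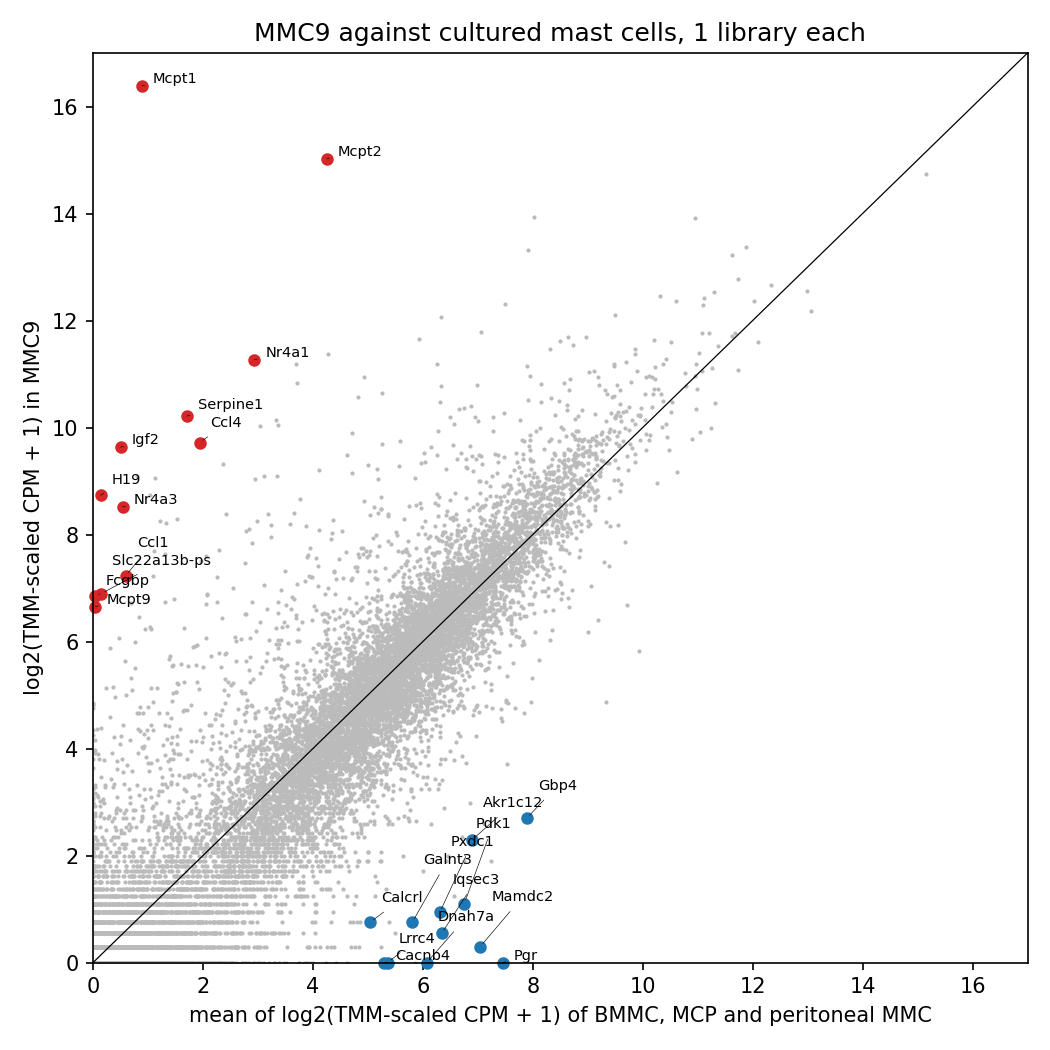
Each gene's log2(TMM-scaled CPM + 1) in MMC9 (y) against its mean in BMMC, MCP and peritoneal MMC (x), 1 library each. Red and blue points are the 12 genes with the largest smallest fold above and below the 3 cultures, the line marks equal levels, and Mcpt1 and Mcpt2 lie farthest above it.

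By size, 267 genes were higher in MMC9 than in each culture and 203 were lower. The other genes with the largest folds above were H19, an imprinted noncoding RNA (chromosome 7, 142575532 to 142578146, 425 CPM, at least 1522-fold above peritoneal MMC), Igf2, its neighbouring growth factor gene (chromosome 7, 142650768 to 142658804, 793 CPM, 961-fold, 506 to 2104, above MCP), the pseudogene Slc22a13b-ps (326-fold, 139 to 1008, above BMMC) and Serpine1, an inhibitor of plasminogen activation (199.8-fold, 161 to 252, above BMMC). H19 had 3, 1 and 0 reads in BMMC, MCP and peritoneal MMC. Lower genes were led by Pgr, the progesterone receptor, with 0 reads in MMC9 and 144, 242 and 153 CPM in BMMC, MCP and peritoneal MMC (at least 209-fold against BMMC). Mamdc2 (248-fold, 44.3 to 9796), Galnt3 (77.6-fold, 26.4 to 377), Pxdc1 (73.8-fold, 28.7 to 271), Iqsec3 (77.1-fold, 21.2 to 639), Lrrc4 (at least 45.5-fold), Calcrl (35.0-fold, 11.8 to 171), Dnah7a (at least 34.1-fold), Gbp4 (33.4-fold, 22.4 to 52.3), Cacnb4 (at least 31.9-fold) and Akr1c12 (24.6-fold, 15.3 to 42.4) were lower by these factors against the nearest culture. For Cacnb4 the fold was 2.84 when the row with most reads stood for the symbol. Pdk1, a kinase that restrains pyruvate oxidation, was 61.2-fold (26.1 to 189) lower than in peritoneal MMC. Of the glycolysis list 1 of 16 members was at least 2-fold lower than in each culture (median log2 difference -1.15, percentile 0), and of the proliferation list 1 of 30 (median log2 difference -0.88, percentile 0). Mean log2(CPM + 1) of the proliferation list was 5.31 in MMC9, 5.35 in peritoneal MMC, 5.94 in MCP and 7.07 in BMMC. MMC9 thus lay near peritoneal MMC and farthest below BMMC. Without BMMC the lower count was 380 and the higher 382. Plain CPM gave 202 higher and 333 lower genes, and the authors' RPKM gave 195 and 348. Which direction held more genes thus depended on the scaling.

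The level of each type 2 cytokine was then set against the Th2 and ILC2 libraries of the same tissue. Il9, a mast cell and T cell growth factor (chromosome 13, 56479277 to 56482246), was at 27.5 CPM (22.8 to 32.8) in MMC9 from 120 reads, at 10.1 CPM (8.47 to 12) in CD4 Th2 cells and at 6.88 CPM (4.96 to 9.30) in ILC2s. MMC9s thus exceeded CD4 Th2 cells 2.71-fold (2.10 to 3.50) and ILC2s 3.99-fold (2.79 to 5.81). The other 6 libraries had 0 Il9 reads, which in MCP allows up to 0.275 CPM and makes the MMC9 level at least 99.8-fold higher than in MCP. The level allowed was highest in CD8 T cells (0.422 CPM), where the bound on the fold is lower. Il13 (chromosome 11, 53631323 to 53634702) was at 547 CPM (525 to 569) in MMC9, 527 CPM (515 to 539.9) in CD4 Th2 cells and 763 CPM (741 to 785) in ILC2s. The interval of the MMC9 to CD4 Th2 ratio, 1.04-fold (0.989 to 1.09), held 1, and against ILC2s the ratio was 0.716-fold (0.682 to 0.753). Il4 (chromosome 11, 53612461 to 53618665) was lower in MMC9, 159 CPM (148 to 172), than in CD4 Th2 cells, 985 CPM (968 to 1002), or ILC2s, 313 CPM (299 to 327). Il5, the eosinophil growth factor (chromosome 11, 53720794 to 53725103), had 7 reads in MMC9 (1.6 CPM, 0.644 to 3.30), against 123 CPM in CD4 Th2 cells and 737 in ILC2s. Areg, an epithelial growth factor, was at 1.6 CPM in MMC9, 1957 in CD4 Th2 cells and 578 in ILC2s, while Csf2 was at 19.9 CPM in MMC9, 3.67 in CD4 Th2 cells and 373 in ILC2s. The type 2 cytokine list had 1 of 7 members at least 2-fold higher than in every intestinal comparator and 1 lower (median log2 difference 0.80, percentile 97.53), and with a pseudocount of 5 its median was -0.0278. In the authors' RPKM, Il9 was 32.9 in MMC9, 13.7 in CD4 Th2 cells and 9.49 in ILC2s. With plain CPM and with RPKM the Il13 ratio to CD4 Th2 cells was 0.836 and 0.920.

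**Figure D3:**
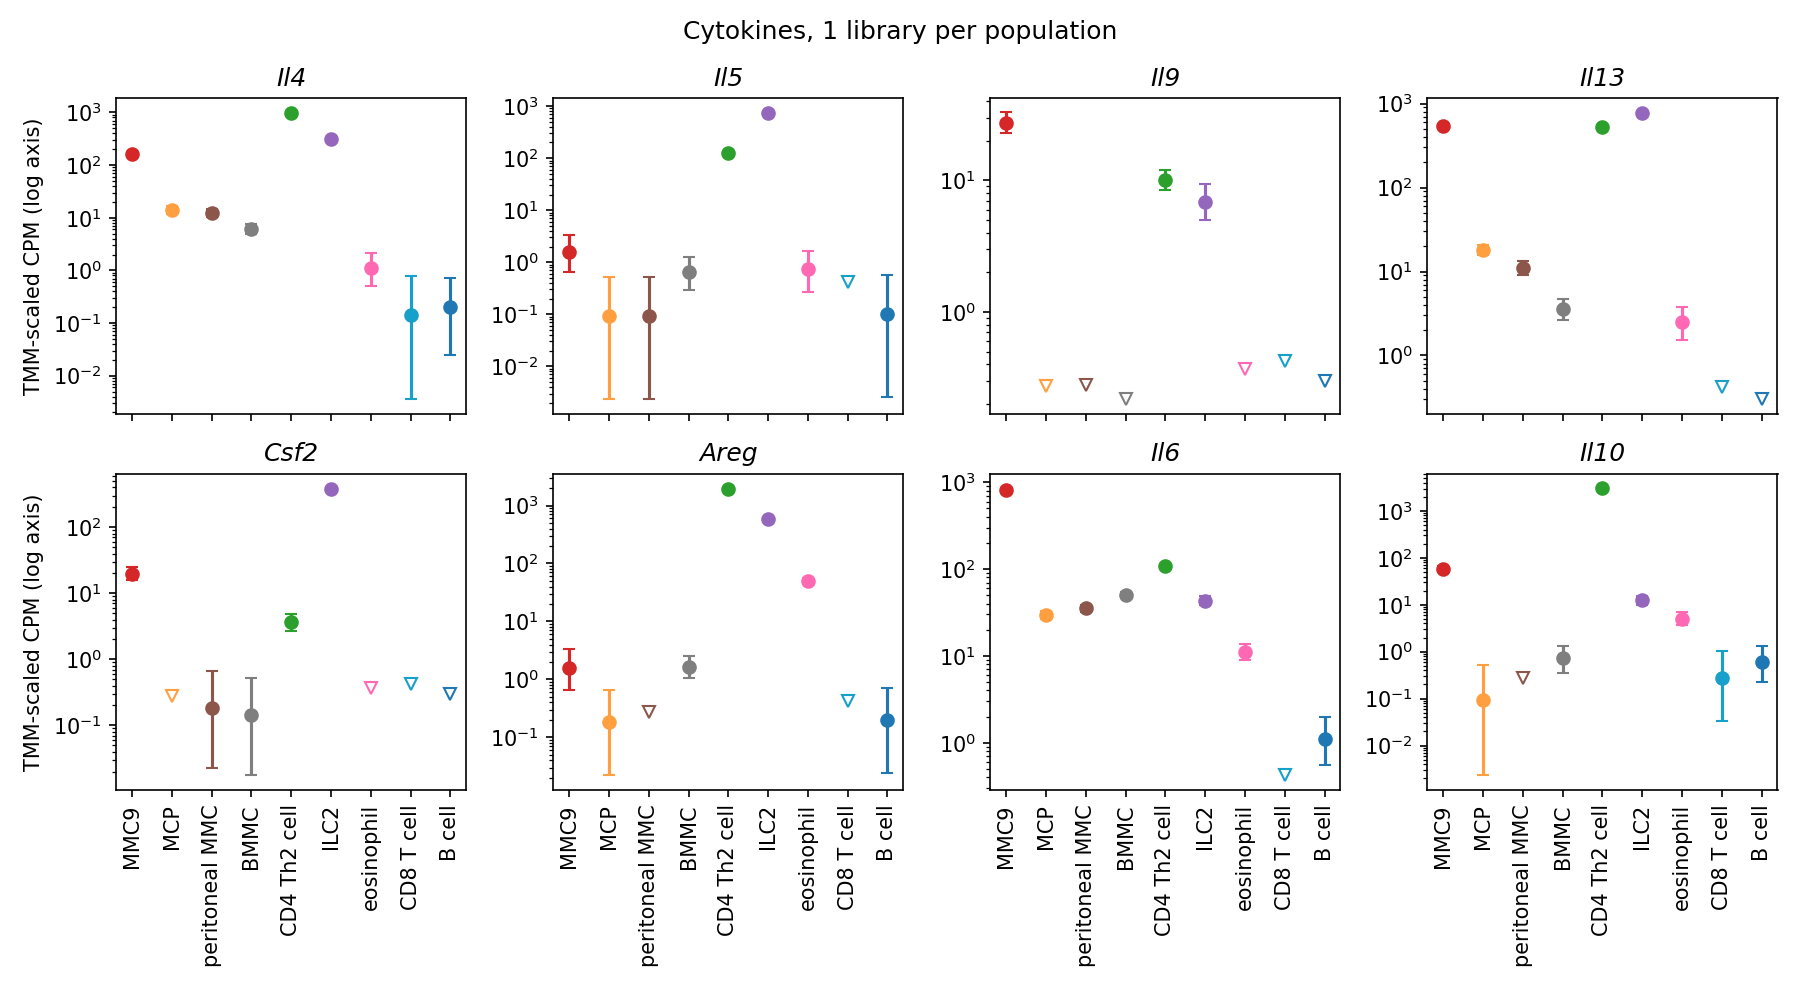
Cytokine levels in the 9 libraries on a log axis of TMM-scaled CPM, drawn as single libraries with 95% exact Poisson intervals (counting error only) and open triangles at the level of 3 reads for 0 reads. Il9 is highest in MMC9 at 27.5 CPM, and Il5 is highest in ILC2 at 737 CPM.

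Against the other libraries sorted from the intestine (CD4 Th2 cells, ILC2s and the library labelled eosinophil, which carried epithelial and stromal genes), 423 genes were higher in MMC9s than in each and 223 were lower. Mast cell genes were among the higher genes: 18 of 20 core members (median log2 difference 7.06, percentile 100), 15 of 17 granule proteases (median log2 difference 5.28, percentile 100), 15 of 25 IgE receptor signalling genes (median log2 difference 3.31, percentile 100) and 11 of 17 amine and eicosanoid genes (median log2 difference 4.11, percentile 100) were at least 2-fold above each comparator. Rab38, a GTPase of lysosome-related organelles with 0 reads in ILC2s, was at least 548-fold higher, Rprm 443-fold (203 to 1211), Chst1 375-fold, Mcpt4 292-fold (270.5 to 315), Mcpt1 283-fold (274 to 292), Gata2 279-fold (237 to 332), Rnf180 276-fold (149 to 578), Gmpr 268-fold (167 to 462), Itga2b 262-fold (215 to 323) and Adora3 250.2-fold (158 to 423) than in the nearest of the 3. Gata2 is a transcription factor of mast cells, and Adora3 an adenosine receptor. For Mcpt4, Mcpt1, Gata2, Rnf180, Gmpr and Itga2b the nearest library was CD4 Th2 cells, with Mcpt4 at 0.343% and Mcpt1 at 0.353% of MMC9. Mast cell RNA carried into that library, weighed in the last paragraph for proteases, could limit these folds. Ccl3 and Tnf were also higher, with Ccl3 at 526 CPM and Tnf at 259 CPM in MMC9, against 3.59 and 4.91 in CD4 Th2 cells and 6.06 and 6.55 in ILC2s. Bcl11b, a T cell and ILC2 transcription factor, had 0 reads in MMC9 (at least 124-fold lower than in the library labelled eosinophil), and the ILC2 list had a median log2 difference -3.32, percentile 0, with 3 of 20 members at least 2-fold below every comparator. The other named lower genes were Pou2af1 (62.3-fold, 24.1 to 229.9), Adam19 (62.2-fold, 26.5 to 192), Mmp25 (146-fold, 26.0 to 5799), Tox (45.9-fold, 17.8 to 169), Zfp326 (135-fold, 24.1 to 5344), Cybb (43.6-fold, 21.1 to 109), Slco3a1 (34.0-fold, 13.1 to 126), Raph1 (33.2-fold, 15.1 to 91.1) and Acvr2a (31.3-fold, 15.0 to 78.3). The library labelled eosinophil had a summed epithelial level of 10652 CPM against 765 in MMC9, of which Anpep gave 515. Without it 573 genes were higher and 465 lower, and without CD4 Th2 cells 577 were lower. Plain CPM gave 330 higher and 293 lower.

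Against lymph node B and CD8 T cells, 905 genes were higher in MMC9s and 502 lower. MMC9s came from the small intestine and these lymphocytes from mesenteric lymph nodes. Population and organ of origin therefore cannot be told apart in this comparison. Mcpt1 was at least 202910-fold, Mcpt2 236831-fold (42506 to 9354380), Tph1 17719.6-fold (8140.4 to 48287), Mcpt4 15695-fold (8534 to 32730.3) and Scin, an actin-severing protein, 13372-fold (4575 to 64844) higher than in the nearer library. Every measured core member (20 of 20) was at least 2-fold higher, as were 15 of 18 cholesterol synthesis genes (median log2 difference 2.02, percentile 100) and 10 of 16 glycolysis genes, with 1 lower (median log2 difference 1.60, percentile 100). Immediate early and stress genes were higher for 24 of 28 members, with 1 lower (median log2 difference 5.03, percentile 100). Epithelial genes were higher for 17 of 20 (3.45, percentile 100) and pancreatic genes for 6 of 9 (3.06, percentile 99.93), with 0 lower. Genes of lymph node homing and recirculation were lower: Sell, or L-selectin (4703-fold, 844 to 185761), Ccr7 (at least 343-fold) and S1pr1 (360.2-fold, 141 to 1323), with Ablim1 (396-fold, 215 to 826) and Cmah (339-fold, 156 to 925). The homing and adhesion list had 10 of 28 members lower and 6 higher (median log2 difference -1.36, percentile 0). Of the T cell list 13 of 19 and of the B cell list 7 of 18 were lower than in both, and 7 of 16 interferon response genes were lower with 3 higher (median log2 difference -1.28, percentile 0.130). Leaving out a comparator can only keep or raise a count under the size rule, and the lower count was 905 without B cells and 1093 without CD8 T cells. Plain CPM gave 766 higher and 780 lower, and RPKM 795 and 693.

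Genes shared by all 4 mast cell libraries were defined by the lowest mast cell level against the highest of the 5 other libraries, with counts under 3 reads in these taken as 3 for the size rule. By this measure 99 genes were higher in mast cells. They included the IgE receptor chains Fcer1a and Ms4a2, carboxypeptidase Cpa3, chymase Cma1, tryptases Tpsb2 and Tpsab1, and the transcription factors Gata1, Gata2, Mitf and Tal1. Rab38, with 0 reads in ILC2s, was at least 323-fold, Rprm 329-fold (151 to 897), Tal1 113-fold (81.2 to 163), Csf2rb2, a receptor chain for IL-3, 97.8-fold (86.6 to 111), Cpa3 96.7-fold (93.0 to 101), Cma1 72.8-fold (66.9 to 79.4), Gp1ba 71.4-fold (47.0 to 114), Itga2b 62.4-fold (51.2 to 77), Ms4a2 61.4-fold (54.4 to 69.5) and Gata2 60.0-fold (50.8 to 71.3) higher. BMMC was the lowest mast cell library for each of these 10, and CD4 Th2 cells were the highest other library. Mast cell RNA carried into the CD4 Th2 library could therefore limit these folds. Cpa3 took 5.30% of reads in MCP, 4.52% in peritoneal MMC and 2.14% in BMMC. Only 18 genes were lower in all 4 mast cell libraries, led by Adam19 (57.8-fold, 35.8 to 99.8), Pou2af1 (22.0-fold, 8.40 to 81.7), Pmepa1 (13.3-fold, 9.26 to 19.6), Jakmip1 (12.1-fold, 8.60 to 17.3) and Akap12 (12-fold, 6.41 to 25.5). The higher count was 196 without BMMC, 168 without MMC9 and 161 without the library labelled eosinophil. The lower count was 60 without BMMC and 49 without the library labelled eosinophil.

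The 3 cultures were compared in pairs. They came from different tissues and differently treated mice, and BMMC grew for 4 weeks against 2 for MCP and peritoneal MMC. Y-linked genes also differed between BMMC and the other cultures. These factors cannot be told apart with 1 library each. Myeloid genes were lower in both MCP and peritoneal MMC than in BMMC, and mast cell core genes were higher. MCP had 375 genes higher and 933 lower than BMMC, and peritoneal MMC had 494 higher and 1024 lower. Mpo, the neutrophil granule peroxidase, was at 4728 CPM in BMMC, 5156-fold (2803 to 10752) above MCP and at least 16938-fold above peritoneal MMC. Against MCP, Ccl9 (2930.2-fold, 1002 to 14211), S100a9 (at least 2001-fold), C3 (2993-fold, 828 to 24721) and Elane (at least 1839.8-fold) followed, and against peritoneal MMC, Thbs1 (at least 7663-fold), Fn1 (at least 3001-fold), Lyz2 (2746-fold, 1393 to 6361) and Prtn3 (3933-fold, 1089 to 32484). All 13 of 13 measured neutrophil genes were at least 2-fold lower in MCP (median log2 difference -6.44, percentile 0) and 13 of 13 in peritoneal MMC. Macrophage and dendritic cell genes were lower for 18 of 19 members in MCP and 17 of 19 in peritoneal MMC, with 1 higher in each. Eosinophil genes were lower for 13 of 16 in MCP and 12 of 16 in peritoneal MMC, with 1 and 3 higher. Proliferation genes were lower for 21 of 30 members in MCP (median log2 difference -1.12, percentile 0) and 29 of 30 in peritoneal MMC (median log2 difference -1.70, percentile 0). Mast cell core genes were higher for 17 of 20 members in MCP, with 2 lower, Tpsab1 and Hdc (median log2 difference 1.54, percentile 100), and 17 of 20 in peritoneal MMC (median log2 difference 1.76, percentile 100). Rgs13, a regulator of G protein signalling in mast cells, was 1087-fold (424 to 3993) above BMMC in MCP and 945-fold (369 to 3469.6) in peritoneal MMC. Tmem132e (at least 269.9-fold), Arhgef28 (161-fold, 54.8 to 787), Zmat4 (at least 148-fold) and the Y-linked gene Uty (88.6-fold, 34.2 to 327) were higher in MCP, and Smoc2 (287-fold, 112 to 1055), Arhgef28 (273-fold, 92.8 to 1325), Slc35f3 (at least 223-fold) and the Y-linked gene Kdm5d (186-fold, 63.3 to 906) in peritoneal MMC.

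MCP and peritoneal MMC resembled each other, with 92 genes higher and 168 lower in MCP. Receptors of connective tissue mast cells marked the peritoneal culture. Mrgprb1 was at 771 CPM in peritoneal MMC and 0.367 in MCP (2103-fold, 821 to 7721), Mrgprx2 at 67.1 and 0.275 (244-fold, 83.1 to 1185), and Mrgprb2, the receptor for basic secretagogues, at 667 and 7.43. Tns1 (325-fold, 127 to 1194), Smoc2 (227-fold, 88.3 to 834) and Cntn4 (427-fold, 76.3 to 16912) were also lower in MCP. Clnk, an adaptor of immune receptors, was 27.8-fold (20.8 to 38.1) higher in MCP, Lgals3bp 27.3-fold (19.1 to 40.4), Mrvi1 24.2-fold (20.9 to 28.0), Ltb4r1, a leukotriene B4 receptor, 22.2-fold (13.9 to 37.8) and C4a 20.1-fold (11.3 to 39.5). The connective tissue list was higher than in BMMC for 10 of 11 members in peritoneal MMC (median log2 difference 2.76, percentile 100) and 7 of 11 in MCP (median log2 difference 1.69, percentile 100), where 3 were lower, Tpsab1, Mrgprb1 and Mrgprx2.

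Genes restricted to 1 population, at least 4-fold above all 8 others (folds are against the nearest of them, or against 3 reads in a library with 0 where that is higher), numbered 1610 over the 9 libraries, and 967 of these belonged to the library labelled eosinophil. Left out, that library no longer counted as a population or as a comparator, and 983 genes met the rule over the other 8 libraries, an alternative chosen after seeing the data. MMC9s had 68 (45 by plain CPM and 43 by RPKM), led by Mcpt1 (283-fold), Mcpt2 (245-fold), Smpx (54.4-fold), Cyp26a1 (47.4-fold) and Serpine1 (42.0-fold), where Cyp26a1 degrades retinoic acid. For Mcpt1 and Mcpt2 the nearest library was CD4 Th2 cells, where carried-over mast cell RNA could limit the fold. BMMC had 166 (263 without the library labelled eosinophil), led by Mpo (2144-fold), Prtn3 (887-fold), Elane (at least 737-fold), Epx (367-fold) and Nov (at least 289-fold). MCP had 10, led by Cdh2 (8.00-fold), Mrvi1 (6.40-fold), Extl1 (5.09-fold), Mfap1a (4.72-fold) and Pira11 (4.58-fold), with Pira11 under 4-fold by plain CPM and by RPKM. Peritoneal MMC had 40, led by Mrgprb1 (104-fold), Mrgprb2 (62.0-fold), Cntn4 (at least 57.1-fold), Vstm2b (34.4-fold) and Mrgprx2 (26.4-fold). B cells had 167, led by Fcer2a (476-fold), Faim3 (464-fold), Cd19 (392-fold), Cr2 (371-fold) and Ms4a1 (306-fold). CD8 T cells had 80, led by Cd8b1 (105-fold), Cd8a (91.7-fold), Lcn4 (at least 70.3-fold), Slc15a2 (67.3-fold) and Crtam (46.5-fold). CD4 Th2 cells had 70, led by Ctla4 (179-fold), Penk (89.6-fold), Ncmap (78.0-fold), Il21 (at least 73.4-fold) and Foxp3 (70.8-fold). ILC2s had 42 (198 without the library labelled eosinophil), led by Ret (283-fold), Colgalt2 (93.7-fold), Cntn1 (66.1-fold), Scel (54.0-fold) and Lrrc52 (100.4-fold, 27.3 to 837), of which Ret is a neurotrophic factor receptor. The library labelled eosinophil was led by Dpt (63.6-fold), Dcn (40.3-fold), Fgfbp1 (38.3-fold), Medag (at least 35.8-fold) and Lum (35.0-fold), and Dpt, Dcn and Lum encode matrix proteins of fibroblasts.

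Levels of the genes used in sorting and of marker lists were read in every library. Cd19 was at 899 CPM in B cells and Cd8a at 1627 in CD8 T cells. Kit was at 3476 CPM in MMC9, 5477 in MCP, 7129 in peritoneal MMC and 915 in BMMC. Itgb7, the beta7 chain that sorted MMC9s as low and MCPs as high, was at 1985 CPM in MMC9 and 357 in the cultured MCP. These are RNA levels, not the surface protein of the sort, and the MCP level was read after 2 weeks of culture. In CD4 Th2 cells Cd4 was at 1191 CPM, Il17rb at 2916 and Gata3 at 2144, beside Foxp3 at 197 and Il10 at 3008. In ILC2s Gata3 was at 2235 CPM, Il17rb at 1859.7 and Icos at 927, while Cd3e was at 24.6. In the library labelled eosinophil, Siglec5 (Siglec-F) was at 21.8 CPM, Ccr3 at 42.9 and the granule gene Epx at 0.744. There Epcam, an epithelial adhesion gene, was at 1959 CPM, Krt8 at 1396, Dcn at 680.0 and Igj, the immunoglobulin joining chain of plasma cells, at 11067. Of the eosinophil list, 9 of 17 detected members were highest in BMMC and 4 of 17 in the library labelled eosinophil, where 24 of 26 epithelial, 12 of 15 stromal and 9 of 10 pancreatic members were highest. The summed epithelial level was 10652 CPM there, 1346 in ILC2, 428 in CD4 Th2 cells and 765 in MMC9. The summed epithelial level of 925 CPM in MCP came almost wholly from Anpep (921 CPM), which mast cells also express here. Plasma cell genes summed to 11636 CPM in the library labelled eosinophil, 8072 in CD4 Th2 cells, 5650.0 in ILC2s and 769.5 in MMC9.

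**Figure D4:**
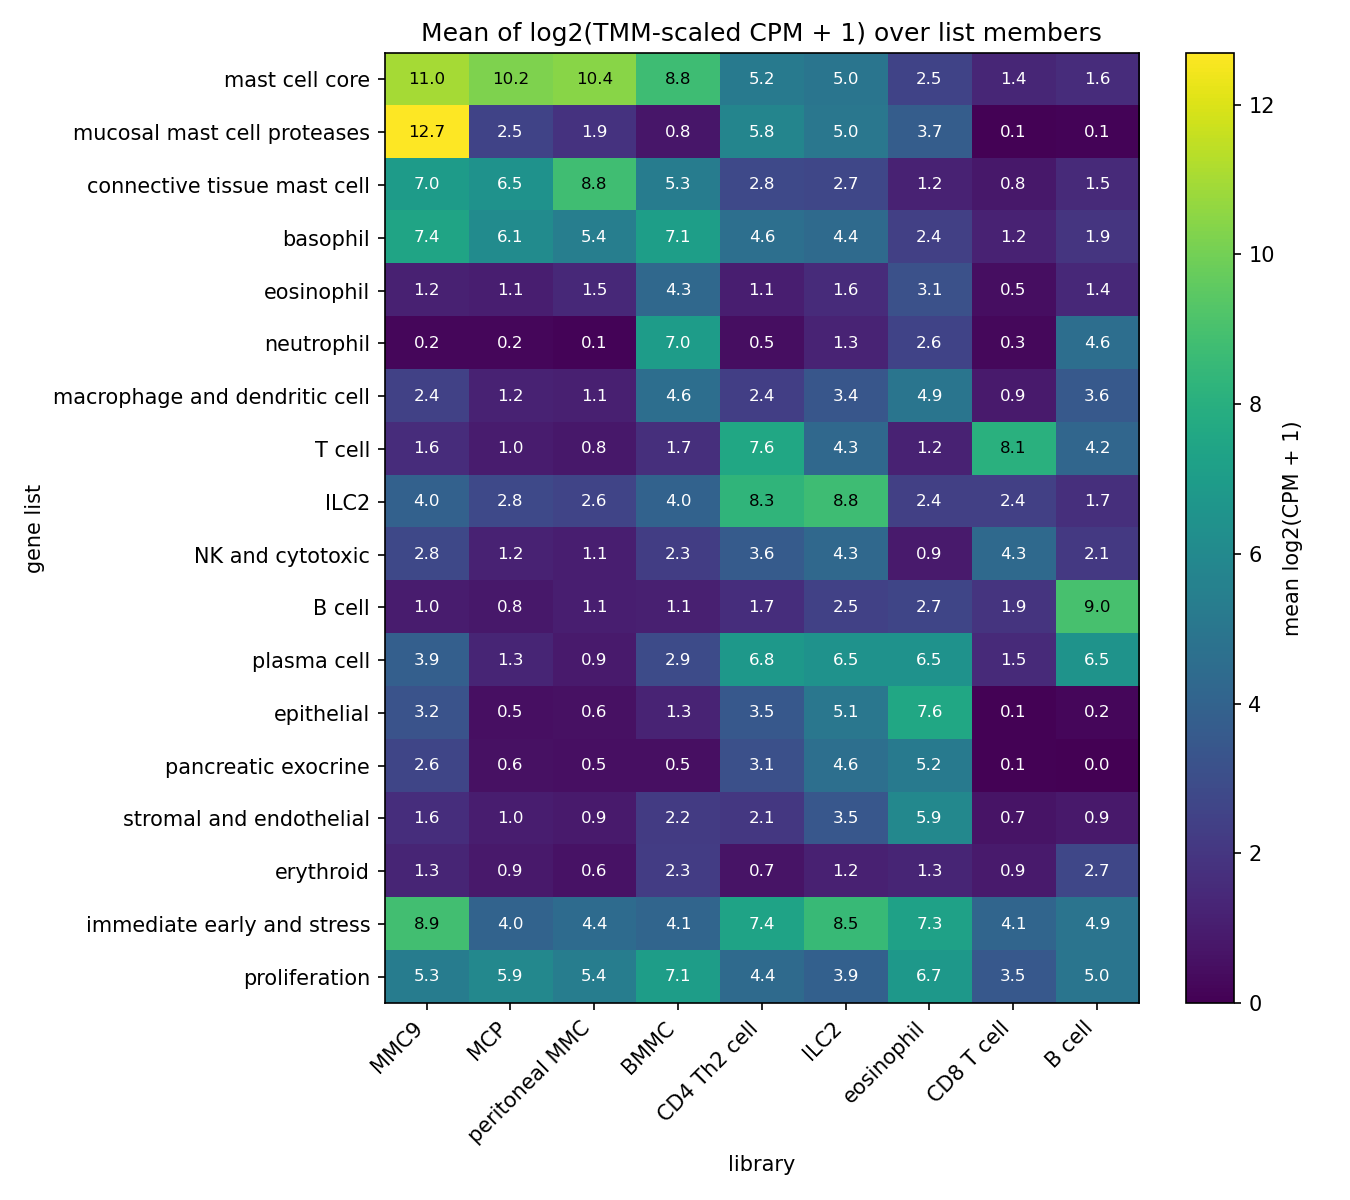
Mean of log2(TMM-scaled CPM + 1) over the members of each marker list (rows) in each library (columns), with the values printed in the cells. The epithelial list averages 7.6 in the library labelled eosinophil and 3.2 in MMC9, and the mast cell core list 11.0 in MMC9.

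Similarity was measured across 14450 genes with at least 10 reads in a library, which are not independent replicates. MMC9 was closest to MCP (Pearson's r 0.913, Spearman's rho 0.912), then to peritoneal MMC (0.893 and 0.896) and BMMC (0.849 and 0.852). It was nearly as close to CD4 Th2 cells (0.841 and 0.848) and ILC2s (0.841 and 0.848) as to BMMC. MMC9s, CD4 Th2 cells and ILC2s were sorted directly from the intestine, while BMMC was cultured. Likeness of population and of isolation cannot be told apart in these values. The closest pair of all was MCP with peritoneal MMC (0.976 and 0.975), followed by CD4 Th2 cells with ILC2s (0.931 and 0.931). B and CD8 T cells stood at 0.897 and 0.902. The library labelled eosinophil was the farthest library from each of the others but ILC2, with rho of 0.597 to peritoneal MMC and 0.670 to MMC9.

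**Figure D5:**
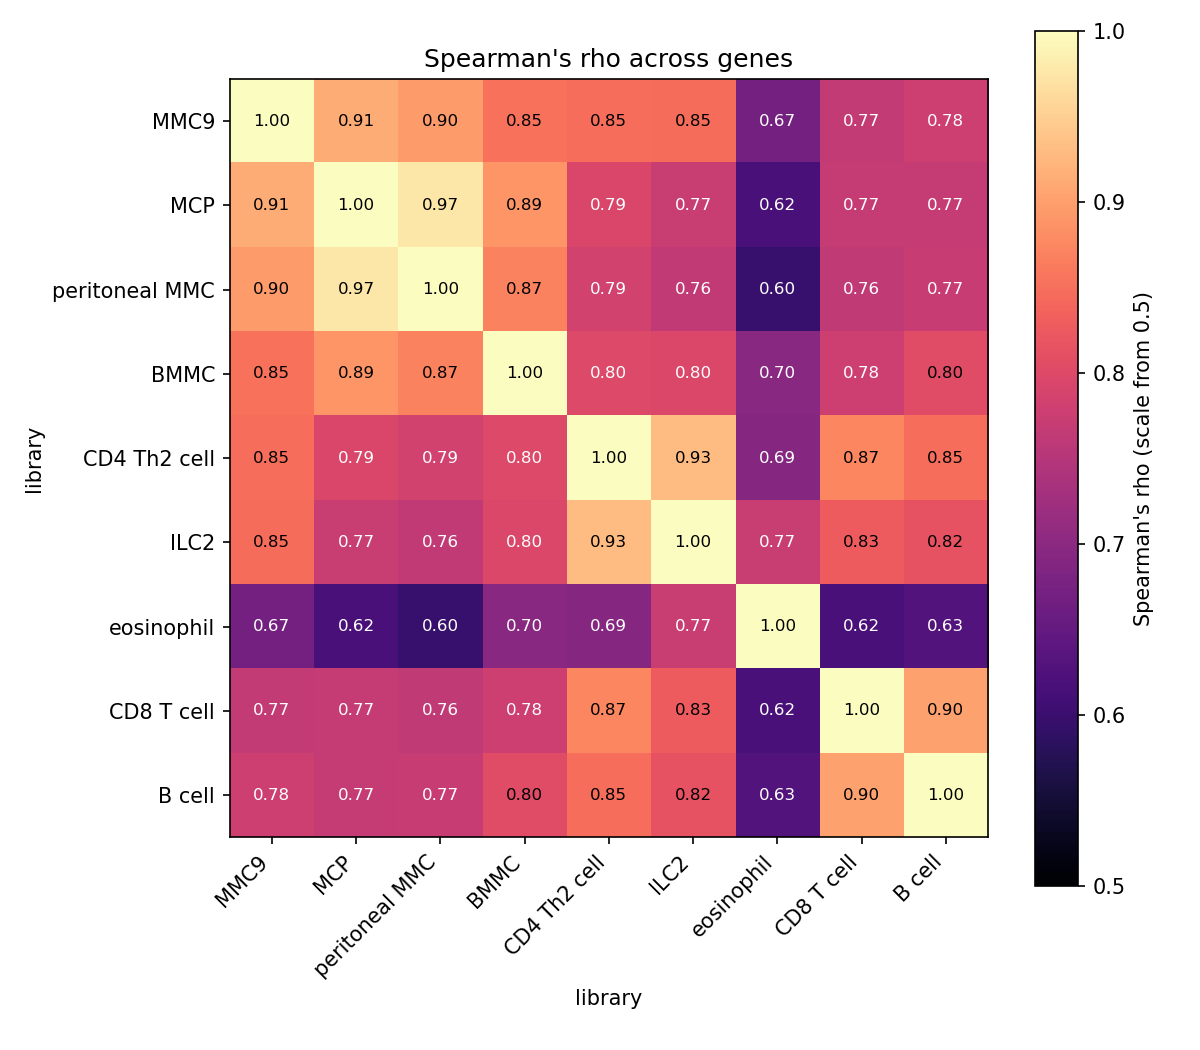
Spearman's rho across genes between each pair of the 9 libraries, on a color scale from 0.5 to 1 with the values printed in the cells. MCP and peritoneal MMC are closest at 0.975, and the library labelled eosinophil with peritoneal MMC is farthest at 0.597.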

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

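The count without the library labelled eosinophil was an alternative chosen after seeing the data, and all others were set beforehand. Gene counts are called moved beyond 1.5 times the main count, and the cause was not tested except where the setting itself loosens or tightens the rule. DESeq2 size factors, the row with most reads per symbol and scaling without the 20 genes of highest share kept every count within 1.5 times. With 10 reads and no CPM minimum the values were 407 for MMC9 vs cultures, higher, 347 for MMC9 vs intestinal cells, lower, 1485 for MCP vs BMMC, lower, 754 for peritoneal vs BMMC, higher, 1583 for peritoneal vs BMMC, lower, 176 for MCP vs peritoneal, higher, 330 for MCP vs peritoneal, lower. At 2-fold the values were 598 for MMC9 vs cultures, higher, 720 for MMC9 vs cultures, lower, 832 for MMC9 vs intestinal cells, higher, 487 for MMC9 vs intestinal cells, lower, 1559 for MMC9 vs lymph node cells, higher, 1329 for MMC9 vs lymph node cells, lower, 212 for shared mast cell genes, higher, 40 for shared mast cell genes, lower, 1214 for MCP vs BMMC, higher, 1639 for MCP vs BMMC, lower, 1468 for peritoneal vs BMMC, higher, 1960 for peritoneal vs BMMC, lower, 359 for MCP vs peritoneal, higher, 540 for MCP vs peritoneal, lower, 2973 for restricted genes. At 8-fold the values were 145 for MMC9 vs cultures, higher, 70 for MMC9 vs cultures, lower, 244 for MMC9 vs intestinal cells, higher, 120 for MMC9 vs intestinal cells, lower, 269 for MMC9 vs lymph node cells, lower, 58 for shared mast cell genes, higher, 11 for shared mast cell genes, lower, 155 for MCP vs BMMC, higher, 209 for peritoneal vs BMMC, higher, 41 for MCP vs peritoneal, higher, 79 for MCP vs peritoneal, lower, 863 for restricted genes. With plain CPM the values were 333 for MMC9 vs cultures, lower, 780 for MMC9 vs lymph node cells, lower, 0.130 for Il4 to CD4 Th2, 0.391 for Il4 to ILC2, 0.836 for Il13 to CD4 Th2, 0.550 for Il13 to ILC2. With RPKM the values were 348 for MMC9 vs cultures, lower, 0.142 for Il4 to CD4 Th2, 0.440 for Il4 to ILC2, 0.920 for Il13 to CD4 Th2, 0.622 for Il13 to ILC2. With 200 reads and 20 CPM the values were 78 for MMC9 vs cultures, lower, 70 for MMC9 vs intestinal cells, lower, 290 for MMC9 vs lymph node cells, lower, 7 for shared mast cell genes, lower, 247 for MCP vs BMMC, higher, 453 for MCP vs BMMC, lower, 318 for peritoneal vs BMMC, higher, 543 for peritoneal vs BMMC, lower, 49 for MCP vs peritoneal, higher, 78 for MCP vs peritoneal, lower, 1048 for restricted genes. With the counting interval wholly past 4-fold the values were 80 for MMC9 vs cultures, lower, 129 for MMC9 vs intestinal cells, lower, 314 for MMC9 vs lymph node cells, lower. Without the library labelled eosinophil the values were 983 for restricted genes. With no filter on low counts the values were 0.914 for rho of MMC9 with its nearest library outside mast cells (ILC2, in place of CD4 Th2 cells). With 100 reads in a library the values were 0.787 for rho of MMC9 with its nearest library outside mast cells (ILC2, in place of CD4 Th2 cells). Leaving out 1 library at a time can only keep or raise the counts of these comparisons. It gave 259 to 380 for MMC9 vs cultures, lower, 317 to 577 for MMC9 vs intestinal cells, lower, 905 to 1093 for MMC9 vs lymph node cells, lower, 102 to 196 for shared mast cell genes, higher, 18 to 60 for shared mast cell genes, lower. List medians that turned direction were -0.18 for cytokine receptors in MMC9 vs cultures (the authors' RPKM), -0.0278 for type 2 cytokines in MMC9 vs intestinal cells (pseudocount 5), 0.78 for T cell in MCP vs BMMC (100 reads in 1 library), 0.0601 for stromal and endothelial in MCP vs BMMC (100 reads in 1 library). Plain CPM moved every MMC9 ratio by -0.62 to -0.30 (log2) and DESeq2 size factors by -0.04 to 0.11. Of 144 folds of named genes under 5 scalings or row choices each, 3 of 720 values fell under 4-fold (Cacnb4 once, Pira11 by both plain CPM and RPKM), 34 moved by over 1.5 times and 0 turned direction. No paired analysis was possible because each population has 1 library. Depth limits low genes most in MMC9, where 3 reads equal 0.686 CPM.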

Other observations

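The tests of carry-over, activation, a mixed sample and an exchange reported here were chosen only after the result was seen. The BMMC culture held transcripts of several other myeloid lineages. Beside Mpo and Elane, the eosinophil granule genes Epx (273 CPM) and Prg2 (246 CPM), the basophil protease Mcpt8 (699.5 CPM), Lyz2 (2044 CPM) and Arg1 (434 CPM) were highest in BMMC of the 9 libraries, and 9 of 13 detected neutrophil members were highest there. MMC9s also carried basophil proteases, with Mcpt8 at 43.0 CPM and Prss34 at 124, against 2.20 and 3.03 in MCP. Neither was 4-fold above each culture, and of the basophil list 2 of 10 members were at least 2-fold higher than in each culture and 2 lower. Cx3cr1, a chemokine receptor, was at 1795 CPM in MMC9, above every other library. The Th2 library paired Il10 (3008 CPM), Ctla4 (9090.2) and Gzma (5223) with Il17a (127). H19 and Igf2 stood at 425 and 793 CPM in MMC9 against 10.5 and 3.74 in CD4 Th2 cells and 1.47 and 21.3 in ILC2s. Xist, expressed from the inactive X, was present in all 9 libraries, 149.7 to 766 CPM, while the Y-linked Ddx3y was at 65.4 CPM in MMC9, 43.2 in MCP, 99.5 in peritoneal MMC, 208 in CD4 Th2 cells and 268 in ILC2s, and at most 0.580 in the other 4. The sex-linked list had a median log2 difference of 4.37 for MCP and 5.09 for peritoneal MMC against BMMC (percentile 100 for each). Against lymph node lymphocytes it was 3.34 (percentile 99.8) for MMC9. Sex of the mice cannot be told apart from population in these comparisons.

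Lists not described above gave these values for MMC9 against the cultured mast cells: basophil (median log2 difference 1.45, percentile 99.99), homing and adhesion (median log2 difference 0.03, percentile 84.5), T cell (median log2 difference 0.71, percentile 99.6), B cell (median log2 difference -0.19, percentile 73.0), plasma cell (median log2 difference 1.53, percentile 99.8), ILC2 (median log2 difference 0.83, percentile 99.99), eosinophil (median log2 difference -0.98, percentile 0.230), macrophage and dendritic cell (median log2 difference -0.63, percentile 8.16), neutrophil (median log2 difference -1.89, percentile 0), NK and cytotoxic (median log2 difference 2.02, percentile 99.9), stromal and endothelial (median log2 difference 0.30, percentile 97.3), erythroid (median log2 difference 0.27, percentile 97.0), cholesterol synthesis (median log2 difference 0.17, percentile 69.8), interferon response (median log2 difference 0.62, percentile 99.9), sort markers (median log2 difference 0.71, percentile 99.3) and sex-linked genes (median log2 difference 0.52, percentile 93.7). The T cell and ILC2 lists share Icos, and the ILC2 list holds Il1rl1, which mast cells express. Mean log2(CPM + 1) of the neutrophil list was 7.00 in BMMC, 0.241 in MMC9, 0.228 in MCP and 0.126 in peritoneal MMC. For the macrophage and dendritic cell list it was 4.57, 2.43, 1.21 and 1.11. Only BMMC stood above MMC9 in both. Of these lists, 0 of 13 and 0 of 19 members were at least 2-fold lower in MMC9 than in each culture, with 0 and 1 higher. For the eosinophil list the means were 4.28 in BMMC, 1.16 in MMC9, 1.08 in MCP and 1.45 in peritoneal MMC.

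Il4, Il9 and Il13 reads in the MMC9 library could come from ILC2s or CD4 Th2 cells carried into the sort. Cells bring all their abundant transcripts, yet 13 abundant ILC2-list genes stood in MMC9 at a median 0.606% of their ILC2 level (upper quartile 4.85%), where Il4, the least demanding cytokine, would need 50.9%, and 13 T cell genes stood at 0.109% of their CD4 Th2 level (upper quartile 0.348%), where Il4 would need 16.2%. Both values argue against carry-over as the source, and Il9 was higher in MMC9 than in either library. A first, wider test over all genes of each library above the cultures gave medians of 15.6% over 247 ILC2 genes and 13.7% over 261 CD4 Th2 genes and did not decide. Of these, 187 ILC2 genes and 141 CD4 Th2 genes lay under the Il4 ratio. The wider set takes in genes such as Irf4 (313 CPM in MMC9 and 306 in ILC2s). Whether such genes account for its medians was not tested. Activation during isolation from the intestine cannot be told apart from the population, since the immediate early list was 5.19 higher (log2) in MMC9 than in the cultures and no other mast cell library was uncultured, and expression by the MMC9s themselves stays open as a hypothesis.

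The library labelled eosinophil held genes of several other cell types. A mixed sample needs several unrelated types at once, and 3 of 4 lists (epithelial, stromal and pancreatic, but not macrophage) had the majority of their detected members highest there, with Olfm4, an intestinal stem cell gene, at 4201 CPM and Igj at 11067. An exchange with another library of the series is argued against: the highest share of a partner's own list was 2.84%, for ILC2. The sort on Siglec-F, CD11b and CCR3 should remove epithelial and stromal cells, so free RNA or a low yield of eosinophil RNA may contribute, which the tables hold no value to decide. A biological explanation was not tested.

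Mast cell transcripts appeared in the CD4 Th2 and ILC2 libraries, with Mcpt1 at 303 and 178 CPM. Carry-over from mast cells of the MMC9 kind would keep proteases in 1 ratio to MMC9. The test took 6 abundant mast cell proteases (Mcpt1, Mcpt2, Mcpt4, Cma1, Cpa3 and Tpsb2) and left out granzymes. Over these 6 the highest and lowest ratio differed 2.66-fold in CD4 Th2 cells (0.343% to 0.912%) and 2.57-fold in ILC2s (0.197% to 0.506%). Both lay within the 4-fold spread allowed for carry-over, a limit set after the result was seen. They were not 1 ratio, since Cma1 and Cpa3 lay above Mcpt1, Mcpt2 and Mcpt4 in both libraries. In CD4 Th2 cells these were 0.912% and 0.719% against 0.343% to 0.408%. Whether mast cells of the MMC9 kind were the only source is therefore not settled. Against the MCP profile the highest and lowest ratio would differ 55674-fold in CD4 Th2 cells. Hdc and Kit in CD4 Th2 cells stood at 11.8% and 12.4% of MMC9, the lower of these 13.0 times the highest protease ratio, which argues against the same source for them. Expression of Hdc and Kit by cells of the Th2 sort stays open, untested. In the library labelled eosinophil Mcpt1 was at 52.3 CPM and Mcpt2 at 22.3, with Cpa3 at 5.58, Tpsb2 at 0.248 and Cma1 at 0.124.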
